A study of Mus musculus with 12 samples.

How the data were processed

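Droplet single-cell RNA sequencing was done on 12 libraries of dissociated mouse brain with CT2A glioma, 3 each in the untreated, RT, 8803 and RT + 8803 groups. Per the labels, whole tumour tissue and Percoll-enriched immune cells were mixed in equal parts. The deposited matrices hold raw whole-number UMI counts per gene and barcode for 32285 genes, with no normalization. Per the file headers they were made with Cell Ranger 8.0.0, while the labels and the series text state 3.1.0 and genome build mm10. The series text says that the authors removed free RNA with SoupX 1.3.0 and doublets with sDblFinder 1.4.0, and kept barcodes of 100 to 5000 UMIs and at most 10% mitochondrial UMIs. The matrices were deposited before those steps. Gene positions were read from GENCODE vM21 (GRCm38), where 32158 of the 32285 gene IDs were found, 31436 of them under the symbol given in the files.

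The libraries held 264023 barcodes, from 485 to 86075 each, and between 581082 and 27655951 UMIs. Barcodes with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs were kept, 50018 in all. The lower limit was set above the stated one, and the upper one dropped, because depth per barcode differs widely between libraries. Scrublet's automatic threshold, run in scanpy, removed 37 cells, far under the rate that droplet loading gives, so doublet calling did not work at that setting. An alternative removed the highest-scoring cells at 0.8% per 1000 cells. The 49981 kept cells were scaled to 10000 UMIs and log-transformed. From 3000 variable genes, 30 principal components were computed and aligned between libraries with an own implementation of the Harmony algorithm. Cells were clustered with the Leiden method (15 neighbours, resolution 1.0, mixed clusters split again at 0.3). The counts themselves were never corrected.

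The 30 clusters were named from 22 marker lists fixed beforehand. A cluster led by haemoglobin and neuronal transcripts together, a cluster led by Lyz1 and Lpl, one with Lyz1 beside cell-cycle genes among its leading genes, mixed B and plasma cell clusters and a pair of proliferating clusters stayed unnamed. Of the 4 clusters named monocyte/macrophage-like, one with 5278 cells raised 7 of 12 markers of that class and 4 of 8 of microglia. Tmem119, Fcrls, C1qa and C1qb were among its 10 leading genes, so microglia-related cells within the class are not excluded. With cells pooled over libraries, it made up 33.7% of the class untreated and 28.92% with 8803. Per library it held 26 of 85, 36 of 278 and 710 of 1928 cells in untreated replicates 1, 2 and 3. With 8803 it held 635 of 2533, 600 of 2193 and 862 of 2525, so the groups overlap. The glioma-like cluster raised 9 of 12 glioma markers (mean log2 fold 2.04) and 5 of 7 fibroblast markers (mean log2 fold 2.41). Only 1 glioma marker was among its 10 leading genes. No reference for CT2A was used.

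For gene tests, UMIs were summed per library and class in 5 classes. A library entered a class with at least 20 of its cells, which left 2 untreated libraries in microglia-like and endothelial-like cells, and 2 each with 8803 and RT + 8803 in glioma-like cells. Genes were filtered with filterByExpr, scaled with TMM factors and tested with edgeR's robust quasi-likelihood F-test in one fit of all groups per class. The contrasts were 8803, RT and RT + 8803 against untreated, RT + 8803 against RT and against 8803, and the interaction of RT and 8803. P-values were adjusted with the Benjamini-Hochberg method within class and contrast, with a threshold of 0.05. Adjusted p-values come from these edgeR fits unless DESeq2 is named. For 20 pathway lists fixed beforehand, limma's camera was run with a preset correlation of 0.01 and again with an estimated one, on lists with at least 5 measured members. Marker lists of other classes were tested the same way.

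Shares of cells were tested with edgeR on kept cells per class and library over 18 classes, beside an exact two-sided permutation test on the shares over 20 assignments, which cannot go under 0.1. The interval printed for the share of a single library is an exact Clopper-Pearson interval at 95%. It covers counting error only.

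Genes were named by a rule fixed before the data were examined. Per class and contrast it takes up to 8 higher and 8 lower genes with the smallest adjusted p, leaving out mitochondrial, ribosomal, haemoglobin and unnamed genes. It adds up to 4 members per pathway list by p, and a set of interferon, p53, proliferation, barrier, microglia, macrophage and T cell genes whatever their p. From the genes so selected, the text gives a part.

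The tests were tried on simulated data with 200 changed genes per class at folds of 1.5, 2 and 4. For 8803 vs untreated in microglia-like cells, 81.8% of genes changed 4-fold, 28.4% of those changed 2-fold and 6.0% of those changed 1.5-fold were called. Over all simulated classes and comparisons, 353 of 2966 calls were false (11.9%, from 2.2% to 32.1% per comparison), more than the 5% that the threshold allows, so lists of called genes hold more false ones than their adjusted p-values state. In shares simulated for 8803 vs untreated, 50.0% of 3-fold changes were called, and 1.73% of unchanged classes.

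Alternatives fixed before the data were examined were DESeq2 size factors, the DESeq2 test, no low-count filter, the replicate number as a block, the stated UMI range, kept doublets, TMM factors over the classes, at least 1000 UMIs, immune cells only, an estimated correlation and leaving out each library in turn. A further 4 were chosen after seeing the data: doublets removed at the expected rate, the 3 libraries with under 1000 cells left out, unnamed clusters left out of the total, and the sex of each library as a term. The submitters' neighbourhood test of abundance was not repeated.

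Tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.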

Results

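Brains of mice carrying CT2A, a mouse glioma cell line, were dissociated, and cells of the whole tumour tissue were mixed in equal parts with immune cells enriched on Percoll before droplet single-cell RNA sequencing. The 12 libraries form 4 groups of 3 replicates: untreated, radiation therapy (RT), 8803, and RT + 8803. 8803 is a small-molecule agonist of STING, the adaptor that links sensing of cytosolic DNA to type I interferon. The labels give neither the doses nor the time points. The measure is the count of unique molecular identifiers (UMIs) per gene and cell. Total counts ran from 581082 UMIs in untreated replicate 1 to 27655951 in RT + 8803 replicate 1. After filtering, 49981 cells were kept. The untreated libraries held 353, 1624 and 6836 of them, the RT libraries 598, 694 and 4410, and the 6 libraries given 8803 between 5223 and 6833 each. Median UMIs per kept cell ran from 670.5 in RT replicate 2 to 8193.5 in untreated replicate 2. Over all barcodes, the median mitochondrial share of a library was 0.77% to 2.94% in the untreated group, 2.37% to 28.4% with RT, 5.53% to 18.3% with 8803, and 14.5% to 18.6% with RT + 8803. The labels do not say that the libraries of a group came from separate animals. Each p-value of a gene or class share below thus measures the spread between these libraries. List p-values also depend on the correlation set or estimated between genes.

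Clusters were named from marker genes, and a class is called "-like" because no sorted reference was used. Genes were tested in microglia-like, monocyte/macrophage-like, T-like, endothelial-like and glioma-like cells. Levels are a gene's UMIs in the class, scaled to a common library total (CPM) and given as mean ± SD over libraries. Isg15 (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818 in GRCm38) and Ifit3 (ENSMUSG00000074896, chromosome 19, 34583531 to 34588731) encode interferon-induced proteins. Cd74 (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652) encodes the invariant chain of MHC class II. Atf3 (ENSMUSG00000026628, chromosome 1, 191170296 to 191218039) encodes a stress-induced transcription factor, and Spock2 (ENSMUSG00000058297, chromosome 10, 60106219 to 60135198) a matrix proteoglycan of brain endothelium. All 5 are annotated as protein-coding. Lyz1 and Lpl, leading genes of an unnamed cluster, were at 317.6 and 455.0 CPM over the named classes of untreated replicate 1 and at 125.1 and 155.1 CPM in untreated replicate 3, against 1.0 to 7.7 and 8.2 to 22.4 CPM in the other 10 libraries. Untreated replicate 3 entered the untreated baseline in all 5 classes with gene tests and untreated replicate 1 in 3 of them, not in microglia-like or endothelial-like cells. How far transcripts of those cells enter the untreated levels of other genes was not tested.

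8803 was compared with no treatment to ask what STING activation alone does to the tumour and its surroundings. Glioma-like cells made up 7.63% ± 2.62 (SD, n = 3) of kept cells in untreated libraries and 0.525% ± 0.377 (SD, n = 3) with 8803, which is 14.5-fold lower (log2 -3.86, adjusted p = 5.2e-04). Monocyte/macrophage-like cells rose from 23.1% ± 5.60 to 38.8% ± 3.26 (log2 0.75, adjusted p = 0.010). That rise was not called under 6 of 21 alternative settings: unnamed clusters left out of the total (log2 0.44, adjusted p = 0.266), without 8803 replicate 1 (log2 0.68, adjusted p = 0.0520), immune cells only (log2 0.29), TMM factors over the classes (0.49), at least 1000 UMIs (0.93) and 100 to 5000 UMIs (0.98). The unnamed clusters, summed, fell from 27.8% ± 8.86 to 11.7% ± 1.36 (log2 -1.25, adjusted p = 5.2e-04). The largest of them, led by haemoglobin and neuronal transcripts, was at 3.40%, 16.6% and 5.72% in untreated replicates 1, 2 and 3 and at 11.5%, 8.63% and 8.65% with 8803. A pair with Lyz1 among their leading genes was at 31.44%, 2.09% and 14.44% untreated and at 0.57%, 1.08% and 1.24% with 8803. T-like cells (9.24% ± 3.25 untreated, 7.76% ± 1.16 with 8803), microglia-like cells (4.90% ± 0.105 and 4.11% ± 0.751) and natural killer-like cells (2.76% ± 0.0980 and 4.90% ± 0.805) did not pass, with adjusted p of 0.596, 0.596 and 0.239. In an exact two-sided permutation test, each of the 3 called shares had p = 0.1, the smallest that 3 libraries against 3 allow.

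**Figure D1:**
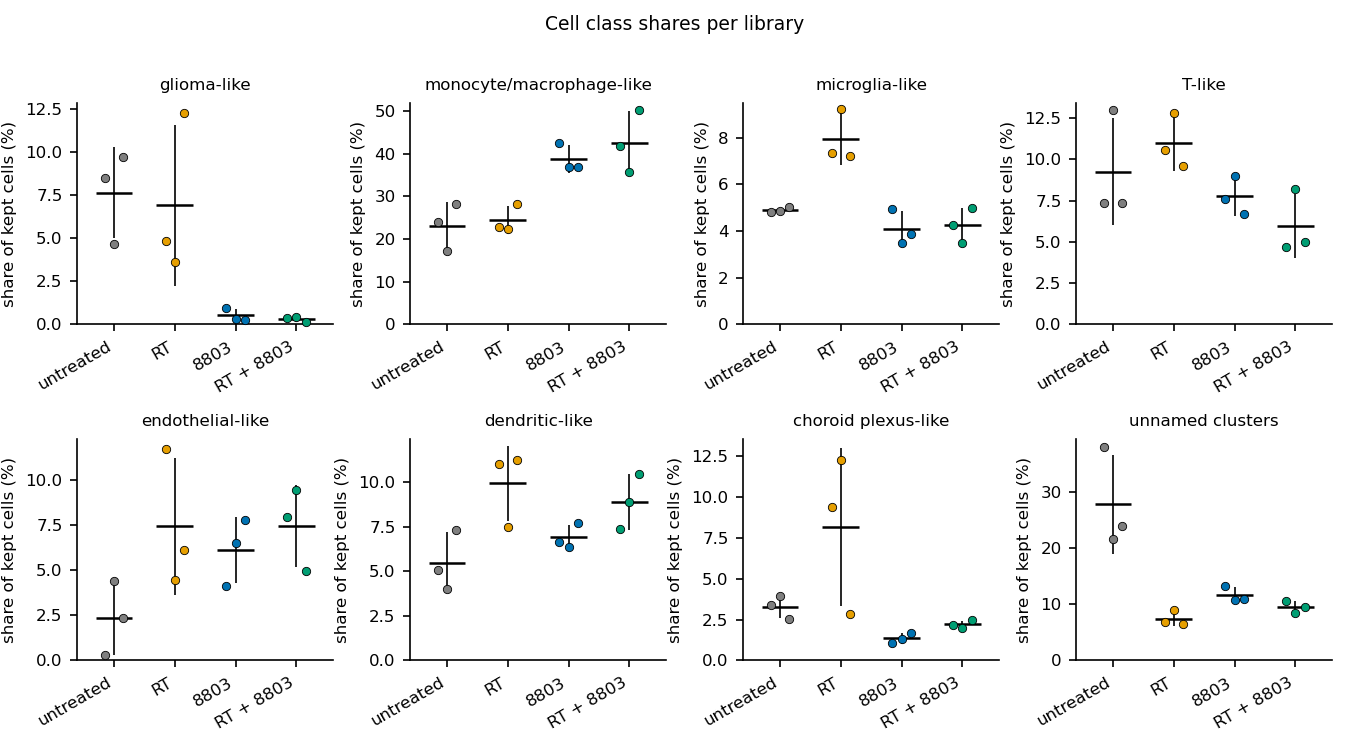
Share of kept cells (%) of 8 cell classes in each of the 12 libraries. Points are libraries, horizontal lines group means and vertical lines 1 SD; the glioma-like share is under 1% in all 6 libraries given 8803 and at least 3.60% in the 6 others.

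In T-like cells, interferon-stimulated genes were higher with 8803. Of 34 measured, 18 rose and 0 fell, and 30 rose when adjusted over the list alone (median log2 1.19, list adjusted p = 1.7e-58, and 0.0060 with an estimated correlation). Isg15 reached 921 ± 105 CPM against 268 ± 75.6 (log2 1.63, adjusted p = 3.3e-04), and Irf7, Usp18, Ifit3 and Ifit3b rose by 1.56, 1.65, 1.80 and 2.09 on the log2 scale. Transcripts of exhaustion and checkpoint genes were lower: 5 of 15 fell, 7 when adjusted over the list alone, and none rose (median log2 -0.58, list adjusted p = 1.6e-08, and 0.0357 with an estimated correlation). Lag3, an inhibitory receptor, fell from 81.0 ± 40.3 to 35.9 ± 6.7 CPM (log2 -1.46, adjusted p = 0.0013), and Rgs16 and Tigit also fell; none of the 3 passed without untreated replicate 2. Gzmb, encoding the cytotoxic protease granzyme B, rose from 962 ± 127 to 1886 ± 165 CPM (log2 0.98, adjusted p = 0.0079), though not without 8803 replicate 2. Pdcd1 (log2 -0.53, adjusted p = 0.284) and Ifng (log2 -0.48, adjusted p = 0.860) did not pass. In all, 133 of 7211 genes passed, 83 up and 50 down. Markers of monocytes and macrophages rose in these T-like cells as well (3 of 7, median log2 1.69, list adjusted p = 5.0e-08, and 0.0093 with an estimated correlation).

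MHC class II genes, which present antigen to helper T cells, fell in monocyte/macrophage-like cells. Of 14 measured, 11 fell and 0 rose (11 when adjusted over the list alone), with a median log2 of -2.45 (list adjusted p = 4.4e-19, but adjusted p = 0.148 with an estimated correlation). Cd74 fell from 10241 ± 5114 to 914 ± 269 CPM (log2 -3.49, adjusted p = 7.3e-05), and H2-Eb1, H2-DMb1 and H2-DMb2 changed by -4.04, -2.45 and -2.36 on the log2 scale. Cell-cycle and thymidine genes fell too: 13 of 25, and 21 when adjusted over the list alone (list adjusted p = 1.3e-20, but adjusted p = 0.148 with an estimated correlation). Mki67, a proliferation marker, fell from 24.8 ± 9.1 to 5.1 ± 1.3 CPM (log2 -2.04, adjusted p = 0.0014) and Ube2c from 15.3 ± 9.5 to 0.5 ± 0.3 CPM (log2 -4.10). Il1b (log2 -2.04), Il12b (-4.01), Cxcl9 (-1.96), Klrb1b (-4.99), Clec9a (-4.54), Itgax (-1.37) and Lag3 (-2.81) fell too. Clec9a and Itgax are dendritic cell genes. Dendritic markers as a list fell in this class (3 of 5, median log2 -3.74, list adjusted p = 1.2e-08, and 0.0389 with an estimated correlation).

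With cells pooled over libraries, one of the 4 clusters of the class held 26.8% of its cells untreated and 40.68% with 8803. Another held 6.63% and 3.54%. Most pooled untreated cells came from untreated replicate 3. Per library, the first cluster held 39 of 85, 94 of 278 and 481 of 1928 cells in untreated replicates 1, 2 and 3. With 8803 it held 1039 of 2533, 891 of 2193 and 1020 of 2525, so the groups overlap. Apart from MHC class II, changes were not tested within clusters. Genes that rose in monocyte/macrophage-like cells with 8803 included Cd24a (58.2 ± 6.7 against 4.7 ± 4.3 CPM; log2 3.03, adjusted p = 6.4e-06), Igfbp6 (log2 2.97), Lipg (5.01), Ctsl (1.65) and Trem2 (1.21). Of 34 interferon-stimulated genes 5 rose and 0 fell, and 12 rose when adjusted over the list alone (median log2 0.83, list adjusted p = 1.1e-16, but adjusted p = 0.236 with an estimated correlation). Microglia markers were higher in this class, 3 of 5 when adjusted over the list alone, with 1 lower (median log2 0.82, list adjusted p = 0.0161, but adjusted p = 0.161 with an estimated correlation). Ifi44 rose from 37.2 ± 17.9 to 118 ± 8.2 CPM (log2 1.38, adjusted p = 0.0023). Isg15 (595 ± 346 untreated, 1335 ± 237 CPM with 8803; adjusted p = 0.134), Cxcl10 (adjusted p = 0.900), Arg1 (0.785) and Mrc1 (0.971) did not pass. In all, 539 of 11946 genes passed, 206 up and 333 down. Apod, a lipocalin of oligodendrocytes and fibroblasts, rose in 3 immune classes by similar amounts: log2 3.21 in monocyte/macrophage-like, 3.06 in microglia-like and 3.03 in T-like cells, where it reached 181 ± 53.9, 208 ± 85.5 and 281 ± 132 CPM.

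In microglia-like cells, Lcn2, encoding the iron-binding acute-phase protein lipocalin-2, rose from 4.8 ± 2.7 (n = 2) to 142 ± 46.1 CPM (n = 3; log2 4.55, adjusted p = 2.1e-08). Lcn2 was also a leading gene of the choroid plexus-like cluster, and whether its counts here come from free RNA of other cells was not tested. Of 34 interferon-stimulated genes 13 rose and 0 fell, and 29 rose when adjusted over the list alone (median log2 0.86, list adjusted p = 1.7e-24, but adjusted p = 0.103 with an estimated correlation). Examples are Rsad2 and Oasl1 (both log2 1.71), Bst2 (1.37), Usp18 (1.35) and Isg15 (1.00). Ly6a (log2 1.88), the MHC class I genes H2-Q6 (1.39) and H2-K1 (1.00), and the p53 targets Cdkn1a (2.32) and Bax (1.35) rose as well. Il1b (log2 -2.12), Il1a (-1.07), Cd83 (-1.64), Egr1 (-1.74), Btg2 (-1.68) and Selenop (-1.46) fell. Of 20 homeostatic microglia genes 3 fell and 9 when adjusted over the list alone (list adjusted p = 7.7e-10, but adjusted p = 0.143 with an estimated correlation); Rhob (log2 -1.32) and Adgrg1 (-1.42) were among them, while P2ry12 (log2 -0.98, adjusted p = 0.0612) and Tmem119 (log2 0.14, adjusted p = 0.860) did not pass. The chemokine gene Cxcl10 did not pass either (adjusted p = 0.916). Markers of monocytes and macrophages rose in these microglia-like cells, 2 of 8 (median log2 2.00, list adjusted p = 3.4e-06, but adjusted p = 0.246 with an estimated correlation), and 3 of 8 microglia markers fell when adjusted over the list alone (median log2 -0.89, list adjusted p = 7.5e-04, but adjusted p = 0.271 with an estimated correlation). In all, 194 of 7094 genes passed, 120 up and 74 down. Untreated replicate 1 had too few microglia-like cells to enter.

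In endothelial-like cells, which line the blood-brain barrier, 922 of 9954 genes passed, 389 up and 533 down (untreated n = 2, 8803 n = 3). Interferon-stimulated genes rose: 23 of 33, and 27 when adjusted over the list alone, with 0 falling (median log2 1.27, list adjusted p = 2.0e-34, and 0.0065 with an estimated correlation). Rsad2 went from 62.2 ± 15.7 to 607 ± 178 CPM (log2 3.39, adjusted p = 5.1e-22) and Ifit3 from 170 ± 18.8 to 890.5 ± 135.3 CPM (log2 2.42). The MHC class I genes H2-Q6 (log2 2.23), H2-K1 (1.37) and B2m (0.87) rose. Of 20 endothelial activation genes, 9 rose and 1 fell, and 10 rose and 2 fell when adjusted over the list alone (median log2 1.10, list adjusted p = 1.7e-06, and 0.0180 with an estimated correlation). They include Ackr1 (log2 2.79), Cd93 (1.70), Icam2 (1.25) and the adhesion molecule gene Vcam1 (1.23). Ctla2a rose from 550 ± 34.0 to 5310 ± 1499 CPM (log2 3.28).

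Of 29 blood-brain barrier genes in endothelial-like cells, 13 fell and 1 rose with 8803, and 15 fell and 1 rose when adjusted over the list alone (median log2 -0.64, list adjusted p = 5.4e-07, but adjusted p = 0.337 with an estimated correlation). Spock2 fell from 1041 ± 203 to 158 ± 63.5 CPM (log2 -2.73, adjusted p = 1.7e-23). The transporter genes Slc22a8 (log2 -2.74), Slc16a1 (-2.17) and Slc7a5 (-1.67) and the membrane protein gene Itm2a (-1.81) fell. The tight junction genes Cldn5 (1971 ± 725 untreated, 2347 ± 344 CPM with 8803; adjusted p = 0.650), Ocln (log2 -0.60, adjusted p = 0.115) and Tjp1 (log2 0.03, adjusted p = 0.961) did not pass, nor did the transporter genes Slc2a1 (adjusted p = 0.893) and Abcb1a (0.953). Mfsd2a, a lipid transporter that limits transcytosis, was at log2 -0.77 (adjusted p = 0.0463) but did not pass under 13 of the alternative settings. Proliferation genes fell, 16 of 24 and 18 when adjusted over the list alone (list adjusted p = 5.3e-20, and 0.0065 with an estimated correlation), with Top2a at log2 -2.78, Mki67 at -3.36 and Tk1 at -4.00. MHC class II genes fell, 8 of 10 (8 when adjusted over the list alone; median log2 -2.30, list adjusted p = 1.4e-25, and 0.0032 with an estimated correlation): Cd74 went from 3341 ± 80.8 to 327 ± 115 CPM. Microglia markers fell in the same cells (5 of 6, median log2 -2.67, list adjusted p = 1.2e-12, and 0.0391 with an estimated correlation), among them P2ry12 (log2 -3.04) and Cx3cr1 (-2.67).

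In glioma-like cells, 25 of 4454 genes passed with 8803, 14 up and 11 down (2 by DESeq2), from 57 and 20 cells in the 2 libraries that entered (untreated n = 3). Frmpd4 rose from 3.5 ± 3.1 to 85.3 ± 62.3 CPM (log2 3.66, adjusted p = 1.4e-06). Htr2c and Enpp2, genes of choroid plexus epithelium, were higher by 3.45 and 2.89 on the log2 scale, and Spry1, an inhibitor of growth factor signalling, was lower (log2 -2.10, adjusted p = 8.5e-04), though these 3 were not called without untreated replicate 2. Of 29 interferon-stimulated genes 1 rose, Ifi44, and 2 when adjusted over the list alone (median log2 0.56, list adjusted p = 5.8e-09, but adjusted p = 0.721 with an estimated correlation). Mki67 did not pass (134.5 ± 68.3 untreated, 89.3 ± 9.8 CPM with 8803; adjusted p = 0.553).

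**Figure D2:**
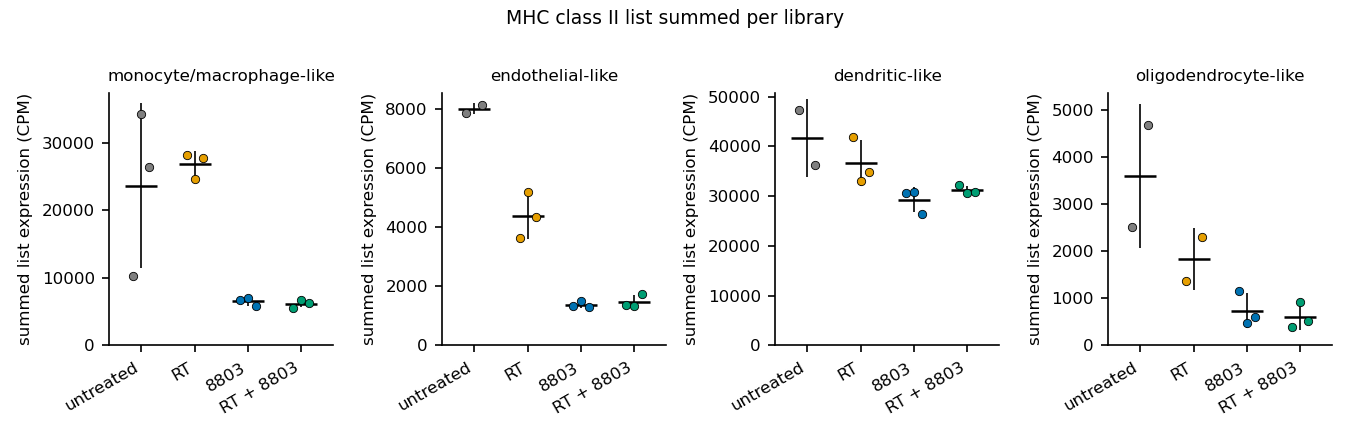
Summed expression (CPM) of the MHC class II list in 4 cell classes, per library, with group means and 1 SD. In monocyte/macrophage-like cells the untreated mean was 23632 and the 8803 mean 6538 CPM.

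RT was compared with no treatment to ask what radiation alone changes. The glioma-like share was 6.90% ± 4.67 (SD, n = 3) with RT, and the difference from the untreated 7.63% ± 2.62 lay within the spread (log2 -0.11, adjusted p = 0.888). The unnamed clusters together fell to 7.42% ± 1.33 (log2 -1.90, adjusted p = 1.1e-05), with the pair that has Lyz1 among its leading genes at 1.84%, 3.75% and 0.75% in RT replicates 1, 2 and 3. Ependymal-like cells (0.329% ± 0.376 untreated, 2.17% ± 0.671 with RT; log2 2.45, adjusted p = 0.0288) and dendritic-like cells (5.48% ± 1.70 and 9.93% ± 2.11; log2 0.85, adjusted p = 0.0330) rose, but were not called under 8 and 15 of the alternative settings. Microglia-like cells were at 7.94% ± 1.11 (log2 0.69, adjusted p = 0.104). By an exact two-sided permutation test the 3 called shares each had p = 0.1, the smallest possible.

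In endothelial-like cells the early-response genes, which stress and tissue dissociation induce within minutes, were higher with RT: 15 of 19 rose and 0 fell, 17 when adjusted over the list alone (median log2 1.85, list adjusted p = 5.9e-75, and 0.0041 with an estimated correlation). Atf3 went from 60.1 ± 24.6 (n = 2) to 1051 ± 311 CPM (n = 3; log2 3.98, adjusted p = 2.1e-26), and Ccn1 (log2 3.98), Nr4a1 (3.45), Ier3 (2.48) and Junb (2.22) rose. Of 24 targets of the DNA damage regulator p53, 5 rose and 0 fell, and 6 rose when adjusted over the list alone (list adjusted p = 7.5e-11, and 0.0334 with an estimated correlation). Cdkn1a, the cell-cycle inhibitor p21, went from 207 ± 50.4 to 993 ± 350 CPM (log2 2.30, adjusted p = 1.5e-11), and Phlda3 (log2 2.48), Btg2 (1.74) and Plk2 (1.38) rose. Icam1, an adhesion molecule of activated endothelium, rose from 51.1 ± 14 to 229 ± 81.2 CPM (log2 2.26, adjusted p = 6.6e-07). Of 24 proliferation genes 4 fell, among them Top2a (75.8 ± 20.9 to 3.2 ± 5.6 CPM), and 15 when adjusted over the list alone (list adjusted p = 2.3e-10, and 0.0076 with an estimated correlation). Neither Top2a nor Phlda3 passed without RT replicate 3. Of 10 MHC class II genes 5 fell, 6 when adjusted over the list alone (list adjusted p = 3.5e-06, and 0.0334 with an estimated correlation), and Apoe (log2 -1.29) and Csf1r (-1.69), genes of myeloid cells, fell as well. Microglia markers fell with them, 1 of 6 and 4 when adjusted over the list alone (median log2 -1.39, list adjusted p = 1.7e-04, but adjusted p = 0.185 with an estimated correlation). Cldn5 did not pass (log2 -0.81, adjusted p = 0.0949). In all, 181 genes passed, 78 up and 103 down.

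Microglia-like cells showed higher early-response genes with RT, 11 of 17 and 13 when adjusted over the list alone (list adjusted p = 4.2e-33, and 0.0268 with an estimated correlation), with Nr4a1 at log2 3.95, Atf3 at 3.22 and Egr1 at 1.71. Inflammatory cytokine and chemokine genes rose: 10 of 20, and 11 when adjusted over the list alone, with 0 falling (median log2 1.87, list adjusted p = 4.5e-29, and 0.0268 with an estimated correlation). Il1a went from 271 ± 7.9 (n = 2) to 1595 ± 267 CPM (n = 3; log2 2.54, adjusted p = 4.9e-07), Il1b rose by 3.19, Tnf by 1.98 and Nfkbiz by 2.13 on the log2 scale. Nlrp3 (log2 2.03), Icam1 (1.61), Csf1 (1.56), Ifrd1 (3.01) and Cdkn1a (3.20) rose. Isg15 (adjusted p = 0.846) and P2ry12 (0.876) did not pass. In all, 113 genes passed upward and 22 downward, and 53 in either direction without RT replicate 3.

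In monocyte/macrophage-like cells, 126 genes passed with RT, 111 up and 15 down, but 14 without RT replicate 3. Nr4a3 went from 5.3 ± 3.3 to 98.8 ± 23.2 CPM (log2 4.59, adjusted p = 7.1e-05), Thbs1, encoding a thrombospondin, from 101 ± 67.5 to 1037 ± 494 CPM (log2 3.21), and Ifrd1 rose by 2.12 on the log2 scale; these 3 also passed without that library. Nr4a1 (log2 2.92), Nr4a2 (3.29), the angiogenic factor gene Vegfa (2.00), Cdkn1a (1.72), Plk2 (1.97) and Nlrp3 (1.75) passed only with it. In T-like cells 20 of 7211 genes passed, 17 up and 3 down. Hilpda (35.0 ± 7.8 to 206 ± 75.2 CPM; log2 2.91, adjusted p = 2.6e-05), Ifitm1 (log2 2.00), Bhlhe40 (1.39), Areg (4.04) and Tnfsf11 (2.11) rose, the last pair not without untreated replicate 2. None of 17 early-response genes passed in T-like cells (3 rose when adjusted over the list alone; adjusted p = 0.625 with an estimated correlation).

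In glioma-like cells, 32 genes passed with RT (20 up and 12 down, 2 by DESeq2; n = 3 and 3). The metallothionein gene Mt2 went from 236 ± 36.1 to 974 ± 218 CPM (log2 1.98, adjusted p = 5.5e-04), and Mt1 rose by 1.42. Cd274, encoding an inhibitory checkpoint ligand, rose from 55.1 ± 11.6 to 183 ± 35.7 CPM (log2 1.76, adjusted p = 0.0012). Fdps, of cholesterol synthesis, fell (log2 -2.30). Without untreated replicate 3 neither Mt2, Mt1 nor Cd274 passed, and without RT replicate 3, which held 540 of the RT group's glioma-like cells, neither Cd274 nor Fdps passed. Of 10 inflammatory cytokine and chemokine genes 1 rose and 7 when adjusted over the list alone (median log2 1.85, list adjusted p = 7.2e-09, and 0.0247 with an estimated correlation). Early-response genes rose with them, 3 of 17 and 6 when adjusted over the list alone (median log2 1.45, list adjusted p = 3.8e-10, but adjusted p = 0.333 with an estimated correlation).

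**Figure D3:**
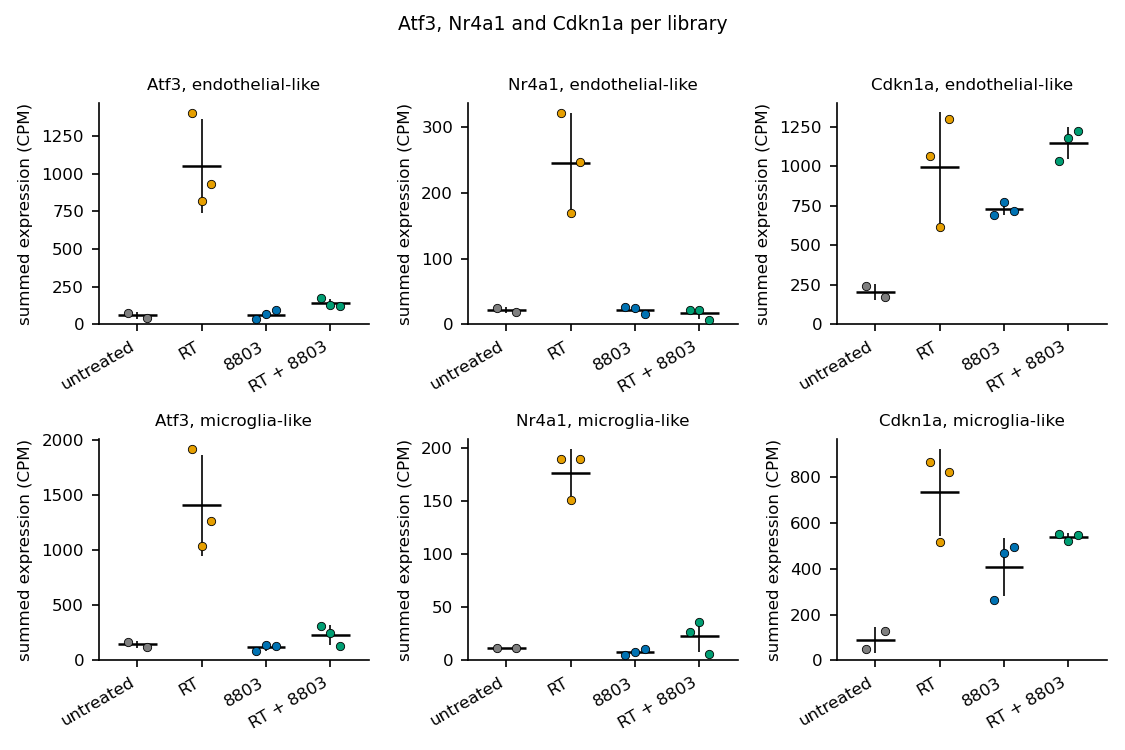
Expression (CPM) of Atf3, Nr4a1 and Cdkn1a per library in endothelial-like and microglia-like cells, with group means and 1 SD. Endothelial-like Atf3 averaged 1051 CPM with RT and 142 CPM with RT + 8803.

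RT + 8803 was compared with no treatment to ask what both agents change together. The glioma-like share was 0.311% ± 0.160 (SD, n = 3), 24.1-fold lower than untreated (log2 -4.59, adjusted p = 9.6e-05). The lowest library, RT + 8803 replicate 3, held 7 such cells of 5223, 0.134% (95% Clopper-Pearson interval 0.0540% to 0.276%; intervals here cover counting error only). Monocyte/macrophage-like cells rose to 42.6% ± 7.31 (log2 0.88, adjusted p = 0.0025), which was not called under 4 of 21 settings, among them unnamed clusters left out of the total (log2 0.54, adjusted p = 0.111). The unnamed clusters together fell to 9.58% ± 1.06 (log2 -1.53, adjusted p = 9.6e-05), but the largest of them was at 9.05%, 6.80% and 7.56%, within its untreated range of 3.40% to 16.6%, and the pair with Lyz1 among its leading genes at 1.22%, 1.26% and 1.63%. Endothelial-like (7.44% ± 2.29; adjusted p = 0.0686) and T-like cells (5.97% ± 1.94; adjusted p = 0.109) did not pass. The exact two-sided permutation p was 0.1 for each of the 3 called shares, the smallest possible. Barcodes removed by the mitochondrial limit alone numbered 16639, 1406 and 755 in RT + 8803 replicates 1, 2 and 3.

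With RT + 8803, interferon-stimulated genes rose in endothelial-like cells (24 of 33, and 31 when adjusted over the list alone; list adjusted p = 4.5e-37, and 0.0035 with an estimated correlation) and in T-like cells (15 of 34, and 26; list adjusted p = 1.1e-50, and 0.0064 with an estimated correlation). They also rose in microglia-like cells (18 of 34, and 28 when adjusted over the list alone; adjusted p = 0.0796 with an estimated correlation) and in monocyte/macrophage-like cells (10 of 34, and 25; adjusted p = 0.202 with an estimated correlation). Markers of monocytes and macrophages rose alongside in T-like cells (2 of 7, median log2 1.72, list adjusted p = 1.3e-06, and 0.0154 with an estimated correlation), in microglia-like cells (2 of 8, median log2 2.08, list adjusted p = 1.8e-06, but adjusted p = 0.224 with an estimated correlation), and in endothelial-like cells (2 of 12, median log2 0.93, list adjusted p = 0.0173, but adjusted p = 0.694 with an estimated correlation). Microglia markers were higher in monocyte/macrophage-like cells (2 of 5, with 1 lower, median log2 0.74, list adjusted p = 0.0112, but adjusted p = 0.123 with an estimated correlation) and lower in microglia-like cells (2 of 8 when adjusted over the list alone, median log2 -0.65, list adjusted p = 0.0138, but adjusted p = 0.552 with an estimated correlation). Isg15 reached 818 ± 53.8 CPM in T-like cells (log2 1.46, adjusted p = 0.0014) and 920 ± 83.3 CPM in microglia-like cells (log2 1.26, adjusted p = 0.0024). Ifit3 was higher by 2.50 in endothelial-like and 1.56 in microglia-like cells on the log2 scale, and Ifi44 by 1.87 in monocyte/macrophage-like cells. Lcn2, also a leading gene of the choroid plexus-like cluster, reached 167 ± 37.8 CPM in microglia-like cells (log2 4.80, adjusted p = 6.9e-09). In monocyte/macrophage-like cells, Cd74 fell to 797 ± 272 CPM (log2 -3.69, adjusted p = 5.8e-05), 10 of 14 MHC class II genes fell (10 when adjusted over the list alone; adjusted p = 0.142 with an estimated correlation), and Cxcl9 (log2 -1.82), Tk1 (-3.94) and Mki67 (-1.80) were lower. The interferon gene Ifnb1 was at 7.5 ± 6.6 against 0.2 ± 0.3 CPM (log2 5.33, adjusted p = 0.0327) and did not pass under 9 of the alternative settings. In T-like cells, Itgae, an integrin of tissue-resident T cells, fell from 59.4 ± 23.4 to 6.2 ± 5.4 CPM (log2 -3.21, adjusted p = 0.0012).

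In endothelial-like cells with RT + 8803, 8 of 24 p53 targets rose and 9 when adjusted over the list alone (list adjusted p = 7.2e-06, and 0.0470 with an estimated correlation): Phlda3 went from 13.5 ± 1.9 to 116 ± 4.1 CPM (log2 2.99, adjusted p = 4.1e-10), Cdkn1a to 1146 ± 99.6 CPM (log2 2.41), and Mdm2 (1.71) and Bax (1.32) rose. Of 29 blood-brain barrier genes 11 fell and 1 rose, and 14 fell and 1 rose when adjusted over the list alone (list adjusted p = 4.6e-07, but adjusted p = 0.328 with an estimated correlation). Spock2 (log2 -2.94), Slc22a8 (-3.33) and Mfsd2a (106 ± 71.9 to 44.2 ± 9.2 CPM; log2 -1.56, adjusted p = 2.1e-05) fell, while Cldn5 did not pass (log2 0.12, adjusted p = 0.860). Vcam1 (log2 1.46) and Ackr1 (2.56) rose, and Cd74 fell by 3.78 and Top2a by 3.77 on the log2 scale. Microglia markers fell in the same cells as well (5 of 6, median log2 -2.62, list adjusted p = 2.2e-11, and 0.0494 with an estimated correlation). Gene counts were 797 in endothelial-like cells (389 up, 408 down), 547 in monocyte/macrophage-like (284 and 263), 158 in microglia-like (111 and 47) and 99 in T-like cells (79 and 20).

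In glioma-like cells, 154 genes passed with RT + 8803 (117 up and 37 down; n = 2 libraries of 21 and 25 cells, untreated n = 3). The genes that rose include Htr2c, which went from 2.2 ± 2.6 to 962 ± 305 CPM (log2 8.25, adjusted p = 6.1e-24), Enpp2 from 4.3 ± 4.3 to 464 ± 56.5 CPM (log2 6.34) and Trpm3 from 50.1 ± 13.7 to 1926 ± 408 CPM (log2 5.45). Htr2c and Enpp2 are genes of choroid plexus epithelium, so genes typical of another cell type moved with the other changes in these few cells. Whether their counts come from such cells was not tested. Cd274 rose to 220 ± 44.9 CPM (log2 2.21, adjusted p = 6.0e-04). Mki67 fell from 134.5 ± 68.3 to 9.7 ± 13.7 CPM (log2 -3.33, adjusted p = 0.0053) and Ube2c by 2.45 on the log2 scale; neither passed in DESeq2. Scaling by DESeq2's size factors moved the median of all genes in this class by up to 0.17 log2, and the direction of none of the 219 called lists over all classes.

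RT + 8803 was compared with RT to ask what adding the agonist to radiation changes. The glioma-like share was 22.3-fold lower (log2 -4.48, adjusted p = 2.4e-04). Monocyte/macrophage-like cells were higher (42.6% ± 7.31 against 24.5% ± 3.36; log2 0.80, adjusted p = 0.0087), a call lost without RT replicate 2. T-like (5.97% ± 1.94 against 10.98% ± 1.67; log2 -0.88, adjusted p = 0.0233), microglia-like (4.25% ± 0.746 against 7.94% ± 1.11; log2 -0.90, adjusted p = 0.0233), choroid plexus-like (2.20% ± 0.231 against 8.14% ± 4.84; log2 -1.86, adjusted p = 0.0152) and ependymal-like cells (0.452% ± 0.0530 against 2.17% ± 0.671; log2 -2.22, adjusted p = 0.0152) were lower (n = 3 each). With the 3 libraries under 1000 cells left out, the choroid plexus-like difference was log2 -0.35 (adjusted p = 0.630, over all settings 1.3e-05 to 0.630), and the RT libraries held 9.37%, 12.2% and 2.81% of such cells. None of these 4 falls was called without RT replicate 1, without RT replicate 2 or without RT + 8803 replicate 1. By an exact two-sided permutation test all 6 had p = 0.1, the smallest possible.

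Early-response genes were lower with RT + 8803 than with RT in endothelial-like cells (15 of 19, and 16 when adjusted over the list alone; list adjusted p = 8.5e-58, and 0.0060 with an estimated correlation). They were also lower in microglia-like cells (12 of 17, and 15; list adjusted p = 1.7e-41, and 0.0297 with an estimated correlation). In endothelial-like cells Atf3 fell to 142 ± 28.5 CPM (log2 -2.86, adjusted p = 3.3e-24), Ccn1 by 3.65, Nr4a1 by 3.72, Junb by 2.57 and Icam1 by 1.19 on the log2 scale, the last not without RT replicate 1. In microglia-like cells Egr1 (log2 -2.42), Fosb (-2.99), Atf3 (-2.56), Cd83 (-3.20), Il1a (-2.66), Il1b (-3.40) and the NF-kappa-B inhibitor gene Nfkbia (-1.91) fell. Il1a was at 244 ± 96.6 against 1595 ± 267 CPM. Effects of sample handling cannot be told apart here. Inflammatory cytokine and chemokine genes in these cells were lower for 10 and higher for 1 of 20, and lower for 12 and higher for 2 when adjusted over the list alone (list adjusted p = 7.3e-15, and 0.0394 with an estimated correlation).

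Interferon-stimulated genes were higher with RT + 8803 than with RT in endothelial-like (25 of 33, and 31 when adjusted over the list alone), microglia-like (24 of 34, and 31) and T-like cells (14 of 34, and 31), with 0 lower and adjusted p of 0.0060, 0.0394 and 0.0031 with an estimated correlation. Irf7, which amplifies interferon production, was higher by 2.57, 2.18 and 2.56 on the log2 scale in these classes, and Ifit3 by 2.22, 2.50 and 2.53. In monocyte/macrophage-like cells 7 of 34 were higher and 31 when adjusted over the list alone (adjusted p = 0.139 with an estimated correlation). Markers of monocytes and macrophages were higher in T-like (1 of 7, median log2 1.83, list adjusted p = 1.9e-05, and 0.0190 with an estimated correlation), microglia-like (1 of 8, median log2 2.14, list adjusted p = 0.0023, but 0.359) and endothelial-like cells (3 of 12, median log2 1.30, list adjusted p = 0.0052, but 0.504). In the monocyte/macrophage-like class, Slfn4 went from 67.2 ± 10.9 to 555 ± 45.3 CPM (log2 3.12, adjusted p = 5.0e-05) and Ly6c2, a marker of inflammatory monocytes, from 1577 ± 326 to 5602 ± 11.4 CPM (log2 1.82, adjusted p = 8.6e-04). Vegfa (log2 -3.65), Lag3 (-5.40), Nr4a3 (-3.71), Cst7 (-2.49), Cd9 (-2.39), Il1b (-2.64) and Cd83 (-3.25) fell. MHC class II genes fell in this class, 10 of 14 and 11 when adjusted over the list alone (list adjusted p = 1.2e-23, and 0.0455 with an estimated correlation), with Cd74 at 797 ± 272 against 11017 ± 1666 CPM. In T-like cells Areg (log2 -4.09), Ifitm1 (-1.55), Hilpda (-2.06) and the homing receptor gene Ccr7 (-2.93) fell, the last pair not without RT replicate 3. In endothelial-like cells Cd93 (log2 1.46), H2-Q7 (2.72) and B2m (1.21) rose and Spock2 (-2.59) and Slc16a1 (-2.70) fell. Cldn5 was higher (2162 ± 137 against 1055 ± 531 CPM; log2 0.93, adjusted p = 0.0068), but not called without RT replicate 2 or RT replicate 3. Counts of genes were 404 in endothelial-like (216 up, 188 down), 367 in monocyte/macrophage-like (132 and 235; 34 without RT replicate 3), 320 in microglia-like (174 and 146) and 57 in T-like cells (38 and 19).

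**Figure D4:**
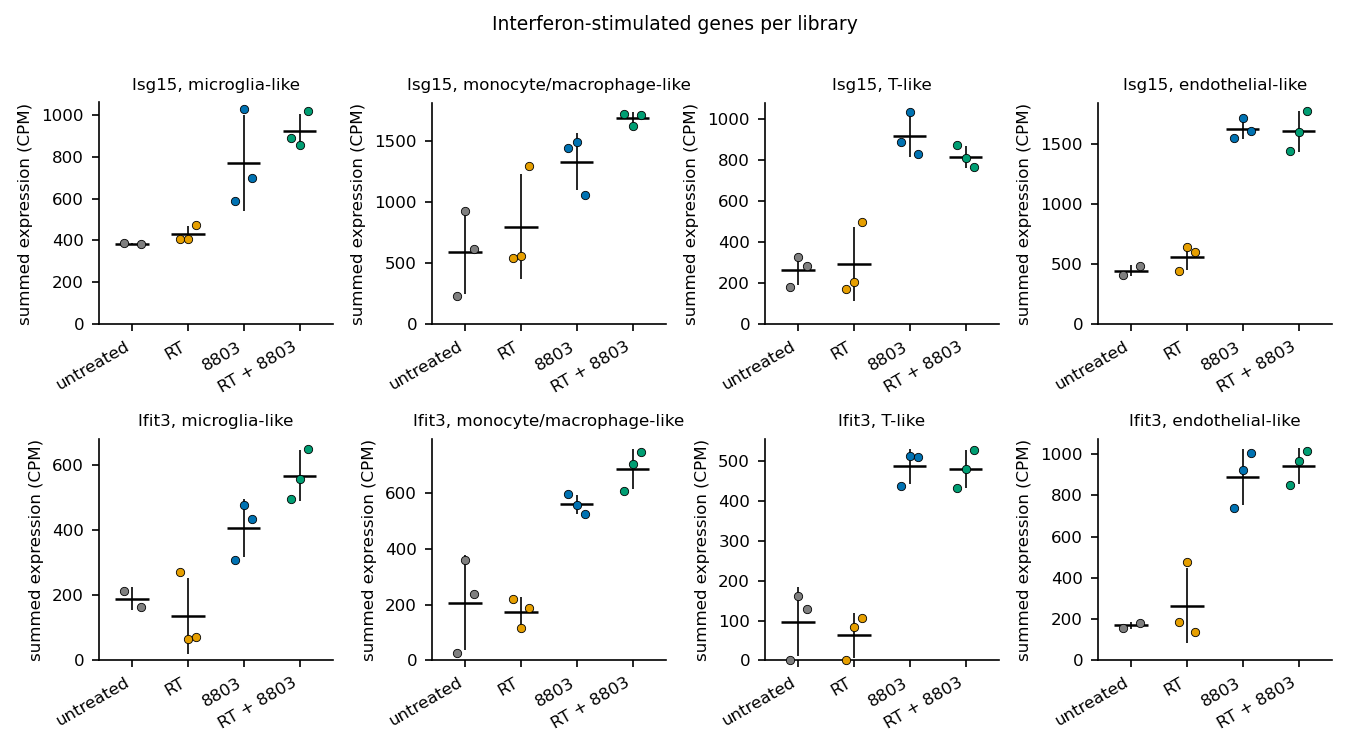
Expression (CPM) of Isg15 and Ifit3 per library in 4 cell classes, with group means and 1 SD. Isg15 in T-like cells averaged 921 CPM with 8803 and 268 CPM untreated.

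RT + 8803 was compared with 8803 to ask what radiation adds to the agonist. In edgeR 0 of 18 class shares passed, and 0 had an unadjusted p under 0.05. Glioma-like cells were at 0.311% ± 0.160 against 0.525% ± 0.377 (log2 -0.74, adjusted p = 0.753). Gene counts in this comparison depend on 8803 replicate 3, without which 42 genes passed in microglia-like, 91 in T-like and 153 in endothelial-like cells, and a split of the 6 libraries across the groups called up to 644 genes in a class, so a low count does not show that RT adds little. In microglia-like cells 0 genes passed in edgeR and 0 in DESeq2, with 222 at an unadjusted p under 0.05 in edgeR, and in monocyte/macrophage-like cells 0 and 0, with 275. In T-like cells 1 gene passed, Nr4a3, a transcription factor induced by receptor signalling (15.3 ± 4.3 to 51.7 ± 13.9 CPM; log2 1.88, adjusted p = 0.0257), which DESeq2 did not call. In endothelial-like cells 22 genes passed in edgeR (19 up and 3 down) and 4 in DESeq2. The p53 target Phlda3 rose from 42.4 ± 14.6 to 116 ± 4.1 CPM (log2 1.40, adjusted p = 1.4e-04), Gdf15, a stress cytokine, from 2.2 ± 0.8 to 23.6 ± 3.3 CPM (log2 3.30, adjusted p = 0.0015), and Ephx1 (log2 1.06) and Wfdc17 (1.11) rose. Of 24 p53 targets 2 rose and 6 when adjusted over the list alone (list adjusted p = 1.6e-10, and 0.0362 with an estimated correlation); Mdm2 did not pass (log2 0.87, adjusted p = 0.128). In glioma-like cells 48 genes passed (44 up and 4 down; n = 2 and 2), led by Htr2c (34.3 ± 9.7 to 962 ± 305 CPM; log2 4.80) and Magi2 (log2 2.76).

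Whether RT and 8803 together differ from the sum of their separate effects was tested as an interaction on the log2 scale. In edgeR, 8 genes passed in microglia-like, 1 in T-like and 6 in glioma-like cells, 91 with a positive and 44 with a negative interaction in endothelial-like cells, and 0 in monocyte/macrophage-like cells (873 at an unadjusted p under 0.05, 29 by DESeq2). In endothelial-like cells 7 of 19 early-response genes had a negative interaction, among them Atf3 (log2 -2.83) and Nr4a1 (-3.70). The count was 15 when adjusted over the list alone (median log2 -1.19, list adjusted p = 4.5e-37, and 0.0139 with an estimated correlation). Handling was not told apart from treatment. In microglia-like cells Ifrd1 (log2 -2.65, adjusted p = 5.0e-04) and Cdkn1a (-2.78, adjusted p = 0.0073) had a negative interaction.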

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

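The tests on the origin of the unnamed cells with Lyz1, apart from the one on shared barcodes, were chosen only after their result was seen.

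For some genes, RT and 8803 given together differed from the sum of their separate effects on the log2 scale, by a test of the interaction itself. In endothelial-like cells 91 genes had a positive and 44 a negative interaction, 8 a negative one in microglia-like and 1 in T-like cells, and 6 a positive one in glioma-like cells. In monocyte/macrophage-like cells 0 passed in edgeR, with 873 at an unadjusted p under 0.05 and 29 by DESeq2. The T-like count of 1 was reached in 17 of 100 splits of the samples. No splits were drawn for endothelial-like, microglia-like and glioma-like cells, where a group lacked a library, so chance was not tested there. Of 19 early-response genes, 7 had a negative interaction in endothelial-like cells (15 when adjusted over the list alone, list adjusted p = 4.5e-37, and 0.0139 with an estimated correlation). Sample handling was not told apart from treatment for them. Negative interaction log2 values in that class include -3.91 for Ccn1, -2.83 for Atf3, -3.70 for Nr4a1 and -2.30 for Ier3. They also include -2.51 for Ifrd1, -2.26 for Sgk1, -2.12 for Apold1 and -2.80 for Hbegf. The genes with a positive one in the same class include Ccl7 at 3.39, C1qa at 2.30, C1qc at 1.92, Tgfbi at 2.75, Fyb at 2.86, Lgmn at 2.19, Ly86 at 2.15 and Ms4a7 at 2.32. Among them, Ccl7, C1qa and Ms4a7 were leading genes of clusters named monocyte/macrophage-like. Whether their counts in endothelial-like cells come from such cells was not tested. Microglia markers as a list were positive there too (1 of 6, median log2 1.76, list adjusted p = 8.1e-04, but adjusted p = 0.255 with an estimated correlation), and against untreated the same list was lower with 8803 (median log2 -2.67), RT (-1.39) and RT + 8803 (-2.62). In microglia-like cells the values were -2.65 for Ifrd1, -2.59 for Rcan1, -2.78 for Cdkn1a, -2.14 for Ell2, -1.77 for Icam1, -3.30 for Zc3h12c, -2.23 for Atf3 and -1.68 for Spag9. T-like Ifitm1 was at -2.75. Glioma-like cells had Htr2c, a gene of choroid plexus epithelium, at 6.56, Pid1 at 4.13, Trpm3 at 3.62, Magi2 at 2.66, Maml2 at 2.52 and Magi1 at 2.45, none of them called without RT replicate 3 or without untreated replicate 3.

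Glioma-like cells were under 1% of kept cells in all 6 libraries given 8803. Whether the mitochondrial limit removed glioma-like cells could not be decided. Barcodes above the limit with at least 500 UMIs and 200 genes were added. The highest of the 6 libraries then held 0.727% (95% interval 0.558% to 0.931%), under the bound of 2.367%. Each added barcode took its class from its 15 nearest kept cells in the same library, where only 7 to 57 cells were glioma-like. A removed glioma-like cell could thus be missed, and barcodes with fewer UMIs were not added. A larger immune fraction alone would leave the share of glioma-like cells among non-immune cells unchanged. That share was 13.8% to 61.2% in the untreated libraries and 1.04% to 6.49% in the 6 given 8803. The ranges do not overlap, which argues against a larger immune fraction as the whole cause. The test against a bound set beforehand did not decide. Among non-immune cells the highest of the 6 was 6.492% (4.954% to 8.33%), against a bound of 6.922% that lies inside the interval, with group means of 38.8% ± 23.8 untreated, 20.8% ± 16.2 with RT, 3.02% ± 3.02 with 8803 and 1.36% ± 0.278 with RT + 8803. The glioma markers summed over all barcodes, a measure chosen after the results were seen, did not fall. They came to 886 ± 258 CPM untreated, 990 ± 102 with 8803 and 967 ± 49.6 with RT + 8803. For most of these markers another class had a higher level than the glioma-like cells. An effect of 8803 on the tumour stays open and was not tested apart from the mitochondrial limit and the immune fraction.

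MHC class II transcripts were lower in monocyte/macrophage-like cells with 8803. A shift between the clusters of the class is excluded as the whole cause, since the list's median was lower within each of the 4 clusters, by log2 -1.43, -1.97, -1.79 and -1.37, and by -1.29 in the class by the same measure. The summed level of the cluster with 5278 cells was 37851 ± 5197 CPM untreated and 6467 ± 656 with 8803, but in another cluster untreated replicate 1, at 3716 CPM, lay below the 8803 libraries at 5112 to 5914. Free RNA from other cells cannot be told apart as a part of it: in oligodendrocyte-like cells, which should lack these genes, the summed level also went from 3597 ± 1527 to 742 ± 363 CPM, a difference of 16.7% of that in monocyte/macrophage-like cells. A biological effect of 8803 stays open, as untested.

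Cells of 2 unnamed clusters with Lyz1 among their leading genes, one with Lpl and one with the cell-cycle genes Birc5 and Pclaf, together made up 31.44%, 2.09% and 14.44% of kept cells in untreated replicates 1, 2 and 3, and 0.57% to 3.75% in the other libraries. In the untreated libraries, the sex transcripts of the library's own mouse reached at most 6.2% of their level in the named classes other than glioma-like cells. That argues against cells of the sampled mouse as the source there, by a limit set after the values were seen. Cells from another source are a candidate explanation on the same measure. The CT2A line carried by the mice is itself such a source, and whether these cells belong to it was not tested. In untreated replicate 3, 21 Y-linked UMIs were counted in these unnamed cells, where the level of the same named classes would give 558.6. The level was also low in RT replicate 3 (9.2%, 1 UMI against 10.8) and 8803 replicate 1 (18.4%, 41 against 222.7). It was 61.4% to 117.8% in the other libraries given RT, 8803 or both. Reads of untreated replicate 3 assigned to the other untreated libraries are excluded, with 0.0% of the barcodes shared. No biological explanation was tested.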

How the results depend on the processing

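Removing doublets at the expected rate, leaving out the 3 libraries under 1000 cells, leaving out unnamed clusters and the sex term were chosen only after the data were seen. The sex term was run for genes only. For gene lists the estimated correlation and the block were run, and DESeq2 size factors for the direction of the called lists, so their dependence on single libraries was not tested.

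The lower share of glioma-like cells was called under each of the 20 settings run for it: with 8803 at log2 -5.44 to -3.55 (adjusted p at most 0.0064), with RT + 8803 against untreated at -5.05 to -4.24 (at most 0.0025) and against RT at -5.91 to -3.74 (at most 0.0059). The rise of monocyte/macrophage-like cells with 8803 was lost under 6 of 21 settings (log2 0.29 to 0.98, adjusted p 4.3e-05 to 0.5485), with RT + 8803 under 4 of 21 against untreated (0.39 to 1.15, 2.3e-06 to 0.4234) and 3 of 21 against RT (0.54 to 1.58, 8.8e-06 to 0.3649). The fall of the unnamed clusters was lost under 1 of 19, the range of 100 to 5000 UMIs. Over all classes, contrasts and settings, 1725 share results stayed on their side of the threshold, 72 lost a call and 33 gained one. Those 1725 can include shares that changed direction without being called in either fit. Of the 281 named gene results that passed, 162 passed under every setting run for them, 82 lost the call under 1 or 2 settings and 37 under 3 or more, and 0 changed sign. Of the counts, 470 stayed within 1.5 times their value and 227 did not.

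With DESeq2 size factors, gene counts in glioma-like cells went from 6 to 11 for interaction of RT and 8803. With the DESeq2 test, gene counts for the interaction went from 8 to 22 in microglia-like and 0 to 29 in monocyte/macrophage-like cells. With the DESeq2 test, gene counts in T-like cells went from 133 to 48 for 8803 vs untreated, 20 to 12 for RT vs untreated, 99 to 32 for RT + 8803 vs untreated, 57 to 32 for RT + 8803 vs RT and 1 to 0 for RT + 8803 vs 8803. With the DESeq2 test, gene counts in endothelial-like cells went from 922 to 470 for 8803 vs untreated, 181 to 113 for RT vs untreated, 797 to 369 for RT + 8803 vs untreated, 22 to 4 for RT + 8803 vs 8803 and 91 up plus 44 down to 83 for interaction of RT and 8803. With the DESeq2 test, gene counts in glioma-like cells went from 25 to 2 for 8803 vs untreated, 32 to 2 for RT vs untreated, 154 to 93 for RT + 8803 vs untreated, 86 to 51 for RT + 8803 vs RT, 48 to 29 for RT + 8803 vs 8803 and 6 to 2 for interaction of RT and 8803. With no low-count filter, gene counts in microglia-like cells went from 158 to 356 for RT + 8803 vs untreated, 0 to 13 for RT + 8803 vs 8803 and 8 to 18 for interaction of RT and 8803. With no low-count filter, gene counts in monocyte/macrophage-like cells went from 539 to 1274 for 8803 vs untreated, 126 to 454 for RT vs untreated, 547 to 1517 for RT + 8803 vs untreated, 367 to 813 for RT + 8803 vs RT, 0 to 23 for RT + 8803 vs 8803 and 0 to 153 for interaction of RT and 8803. With no low-count filter, gene counts in T-like cells went from 133 to 301 for 8803 vs untreated, 20 to 75 for RT vs untreated, 99 to 312 for RT + 8803 vs untreated, 57 to 133 for RT + 8803 vs RT, 1 to 9 for RT + 8803 vs 8803 and 1 to 12 for interaction of RT and 8803. With no low-count filter, gene counts in glioma-like cells went from 25 to 52 for 8803 vs untreated, 32 to 92 for RT vs untreated, 154 to 350 for RT + 8803 vs untreated, 86 to 220 for RT + 8803 vs RT and 48 to 148 for RT + 8803 vs 8803.

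With replicate number as block, gene counts in microglia-like cells went from 194 to 317 for 8803 vs untreated, 158 to 272 for RT + 8803 vs untreated and 0 to 5 for RT + 8803 vs 8803. With replicate number as block, gene counts in monocyte/macrophage-like cells went from 539 to 310 for 8803 vs untreated, 126 to 75 for RT vs untreated, 547 to 328 for RT + 8803 vs untreated and 367 to 240 for RT + 8803 vs RT. In T-like cells they went from 20 to 12 for RT vs untreated and 1 to 0 for RT + 8803 vs 8803. With replicate number as block, gene counts in glioma-like cells went from 25 to 13 for 8803 vs untreated, 32 to 15 for RT vs untreated, 154 to 95 for RT + 8803 vs untreated and 86 to 47 for RT + 8803 vs RT. With replicate number as block, called class shares went from 3 to 5 for RT + 8803 vs untreated. With 100 to 5000 UMIs, gene counts in microglia-like cells went from 194 to 29 for 8803 vs untreated, 113 up plus 22 down to 48 for RT vs untreated, 158 to 49 for RT + 8803 vs untreated and 8 to 1 for interaction of RT and 8803. With 100 to 5000 UMIs, gene counts in monocyte/macrophage-like cells went from 126 to 209 for RT vs untreated, 547 to 844 for RT + 8803 vs untreated, 367 to 607 for RT + 8803 vs RT and 0 to 22 for interaction of RT and 8803. With 100 to 5000 UMIs, gene counts in T-like cells went from 133 to 46 for 8803 vs untreated, 20 to 1 for RT vs untreated, 99 to 18 for RT + 8803 vs untreated, 57 to 98 for RT + 8803 vs RT, 1 to 0 for RT + 8803 vs 8803 and 1 to 0 for interaction of RT and 8803. With 100 to 5000 UMIs, gene counts in endothelial-like cells went from 922 to 234 for 8803 vs untreated, 181 to 47 for RT vs untreated, 797 to 190 for RT + 8803 vs untreated, 22 to 1 for RT + 8803 vs 8803 and 91 up plus 44 down to 32 for interaction of RT and 8803. With 100 to 5000 UMIs, gene counts in glioma-like cells went from 32 to 8 for RT vs untreated. With 100 to 5000 UMIs, called class shares went from 3 to 1 for 8803 vs untreated, 3 to 0 for RT vs untreated, 3 to 1 for RT + 8803 vs untreated and 6 to 1 for RT + 8803 vs RT. With expected-rate doublet removal, gene counts in endothelial-like cells went from 22 to 78 for RT + 8803 vs 8803. In glioma-like cells they went from 32 to 49 for RT vs untreated.

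With small libraries left out, gene counts in monocyte/macrophage-like cells went from 539 to 839 for 8803 vs untreated and 547 to 827 for RT + 8803 vs untreated. With small libraries left out, gene counts in T-like cells went from 133 to 246 for 8803 vs untreated and 1 to 2 for RT + 8803 vs 8803. With small libraries left out, gene counts in endothelial-like cells went from 22 to 9 for RT + 8803 vs 8803. With small libraries left out, gene counts in glioma-like cells went from 25 to 54 for 8803 vs untreated, 154 to 241 for RT + 8803 vs untreated and 48 to 87 for RT + 8803 vs 8803. With small libraries left out, called class shares went from 3 to 1 for RT vs untreated, 3 to 6 for RT + 8803 vs untreated and 6 to 1 for RT + 8803 vs RT. With a sex term, gene counts in microglia-like cells went from 0 to 3 for RT + 8803 vs 8803 and 8 to 14 for interaction of RT and 8803. With a sex term, gene counts in T-like cells went from 20 to 13 for RT vs untreated. In endothelial-like cells they went from 22 to 39 for RT + 8803 vs 8803. With a sex term, gene counts in glioma-like cells went from 48 to 77 for RT + 8803 vs 8803 and 6 to 20 for interaction of RT and 8803. With immune cells only, called class shares went from 3 to 1 for 8803 vs untreated, 3 to 0 for RT vs untreated and 6 to 3 for RT + 8803 vs RT. With unnamed clusters left out, called class shares went from 3 to 1 for 8803 vs untreated and 3 to 0 for RT vs untreated. With an estimated correlation, called gene lists went from 44 to 7 for 8803 vs untreated, 36 to 15 for RT vs untreated, 40 to 7 for RT + 8803 vs untreated, 45 to 15 for RT + 8803 vs RT, 26 to 1 for RT + 8803 vs 8803 and 28 to 7 for interaction of RT and 8803.

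Gene counts in microglia-like cells ranged, for 8803 vs untreated, 74 (without 8803 replicate 2) to 328 (without 8803 replicate 1) and, for RT vs untreated, 53 (without RT replicate 3) to 202 (without 8803 replicate 3). They ranged, for RT + 8803 vs untreated, 75 (without RT + 8803 replicate 3) to 288 (without 8803 replicate 3). For RT + 8803 vs RT, they ranged 92 (without RT replicate 3) to 385 (without 8803 replicate 3). They ranged, for RT + 8803 vs 8803, 0 (without 8803 replicate 2) to 42 (without 8803 replicate 3). For interaction of RT and 8803, they ranged 3 (without 8803 replicate 2) to 25 (without 8803 replicate 1). Gene counts in monocyte/macrophage-like cells ranged, for 8803 vs untreated, 250 (without 8803 replicate 2) to 795 (without untreated replicate 2) and, for RT vs untreated, 14 (without RT replicate 3) to 238 (without untreated replicate 1). They ranged, for RT + 8803 vs untreated, 208 (without RT + 8803 replicate 1) to 1081 (without 8803 replicate 3). For RT + 8803 vs RT, they ranged 34 (without RT replicate 3) to 649 (without untreated replicate 1). They were 0 throughout for RT + 8803 vs 8803. For interaction of RT and 8803, they ranged 0 (without 8803 replicate 1) to 21 (without untreated replicate 1). Gene counts in T-like cells ranged, for 8803 vs untreated, 43 (without untreated replicate 2) to 286 (without 8803 replicate 3) and, for RT vs untreated, 4 (without untreated replicate 2) to 63 (without 8803 replicate 3). They ranged, for RT + 8803 vs untreated, 17 (without untreated replicate 2) to 257 (without 8803 replicate 3). For RT + 8803 vs RT, they ranged 20 (without RT + 8803 replicate 2) to 121 (without 8803 replicate 3). They ranged, for RT + 8803 vs 8803, 0 (without 8803 replicate 1) to 91 (without 8803 replicate 3). For interaction of RT and 8803, they ranged 1 (without 8803 replicate 1) to 11 (without RT replicate 3). Gene counts in endothelial-like cells ranged, for 8803 vs untreated, 662 (without 8803 replicate 2) to 976 (without RT + 8803 replicate 3) and, for RT vs untreated, 102 (without RT replicate 1) to 196 (without RT + 8803 replicate 3). Gene counts in endothelial-like cells ranged, for RT + 8803 vs untreated, 504 (without RT + 8803 replicate 2) to 883 (without 8803 replicate 3) and, for RT + 8803 vs RT, 227 (without RT replicate 3) to 477 (without untreated replicate 3). Gene counts in endothelial-like cells ranged, for RT + 8803 vs 8803, 7 (without RT + 8803 replicate 1) to 153 (without 8803 replicate 3) and, for interaction of RT and 8803, 84 (without RT replicate 3) to 166 (without 8803 replicate 1). Gene counts in glioma-like cells ranged, for 8803 vs untreated, 2 (without untreated replicate 2) to 69 (without RT + 8803 replicate 2) and, for RT vs untreated, 1 (without untreated replicate 3) to 134 (without RT + 8803 replicate 2). Gene counts in glioma-like cells ranged, for RT + 8803 vs untreated, 40 (without untreated replicate 3) to 200 (without 8803 replicate 1) and, for RT + 8803 vs RT, 5 (without RT replicate 3) to 124 (without 8803 replicate 1). Gene counts in glioma-like cells ranged, for RT + 8803 vs 8803, 8 (without untreated replicate 3) to 59 (without untreated replicate 1) and, for interaction of RT and 8803, 0 (without RT replicate 3) to 16 (without untreated replicate 1). Called class shares ranged, for 8803 vs untreated, 2 (without 8803 replicate 1) to 5 (without RT replicate 3) and, for RT vs untreated, 1 (without 8803 replicate 2) to 5 (without RT replicate 3). Called class shares ranged, for RT + 8803 vs untreated, 3 (without 8803 replicate 1) to 5 (without untreated replicate 3) and, for RT + 8803 vs RT, 1 (without RT replicate 2) to 6 (without 8803 replicate 1). Called class shares ranged, for RT + 8803 vs 8803, 0 throughout.

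Leaving out libraries gives fewer samples by construction, and a lone library left in a group is assumed to vary like the other groups. For the other settings the cause was not tested. The replicate numbers do not pair the libraries: the median correlation between deviations of libraries with the same number lay between -0.02 and 0.02 in the 5 classes, and only 2 to 4 libraries per class were closest to one of their own number, so the block is no paired design. Depth limits the smallest sums: T-like cells of untreated replicate 1 had 26 cells and 19720 UMIs, endothelial-like cells of RT replicate 2 had 31 and 20407, and glioma-like cells of RT + 8803 replicate 2 had 25 and 22865.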

Other observations

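The sum of glioma markers over all barcodes and the reading of sex were chosen only after the results were seen. Exhaustion and checkpoint genes were lower with RT + 8803 than with RT in monocyte/macrophage-like cells: 5 of 9 fell, and 6 when adjusted over the list alone (median log2 -0.99, list adjusted p = 2.5e-12, and 0.0136 with an estimated correlation). The same list fell in T-like cells, 3 of 15 and 8 when adjusted over the list alone (median log2 -0.87, list adjusted p = 3.0e-10, and 0.0075 with an estimated correlation). It rose with RT alone in monocyte/macrophage-like cells, 3 of 9 and 4 when adjusted over the list alone (median log2 0.73, list adjusted p = 7.7e-07, and 0.0382 with an estimated correlation). Genes of disease-associated microglia rose there with RT, 2 of 20, and 10 rose and 1 fell when adjusted over the list alone (median log2 0.67, list adjusted p = 9.4e-08, and 0.0382 with an estimated correlation).

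MHC class I genes were higher in endothelial-like cells with RT + 8803 than with RT, 9 of 21 and 17 when adjusted over the list alone (median log2 0.82, list adjusted p = 8.3e-21, and 0.0155 with an estimated correlation). Proliferation genes were lower in these cells with RT + 8803 than untreated, 15 of 24 and 23 when adjusted over the list alone (median log2 -1.70, list adjusted p = 5.9e-26, and 0.0026 with an estimated correlation). Homeostatic microglia genes fell in the same class with 8803, 13 of 18, with 1 rising (median log2 -1.95, list adjusted p = 5.3e-20, and 0.0224 with an estimated correlation).

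The 12 glioma markers, summed over all barcodes, came to 886 ± 258 CPM untreated, 1295 ± 395 with RT, 990 ± 102 with 8803 and 967 ± 49.6 with RT + 8803 (n = 3 each), with no fall beside the lower share of glioma-like cells. For 8 of the 12, another class had a higher level than the glioma-like cells. Xist was higher than Y-linked transcripts in RT + 8803 replicate 1, 8803 replicate 1, RT replicate 2 and untreated replicate 2. Y-linked transcripts were higher in the other 8 libraries, so each group holds libraries of both kinds. Some libraries carried both: untreated replicate 2 had Xist at 292.3 and Y-linked transcripts at 11.9 CPM. RT replicate 1 had 44.6 and 176.3 CPM. Whether a library came from a single animal was not tested.

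Each comparison with 3 libraries per group was repeated on all 10 splits of its libraries; the real split is among the 10, so the smallest possible share is 0.1 and none under 0.05 can be had. Numbers are the real count, then the highest of the other splits. For microglia-like cells, RT + 8803 vs RT gave 320 and 0 genes, and 13 and 8 lists, with 1 split as large for each. Monocyte/macrophage-like cells had 539 and 2 genes for 8803 vs untreated, 126 and 27 for RT vs untreated, 547 and 0 for RT + 8803 vs untreated and 367 and 0 for RT + 8803 vs RT, each with 1 split as large. Their lists were 10 and 11, 5 and 12, 9 and 9, and 10 and 8, with 3, 7, 2 and 1 splits as large. T-like cells in that order had 133 and 69, 20 and 87, 99 and 0, and 57 and 0 genes (1, 2, 1 and 1 splits as large), and 9 and 8, 7 and 5, 6 and 8, and 7 and 9 lists (1, 1, 6 and 3). Endothelial-like cells had 404 and 10 genes and 12 and 13 lists for RT + 8803 vs RT (1 and 2 splits). Glioma-like cells had 32 and 36 genes and 3 and 7 lists for RT vs untreated (2 and 6 splits).

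For RT + 8803 vs 8803, the split of RT + 8803 replicates 1 and 2 with 8803 replicate 3 from the other 3 gave 644 genes in monocyte/macrophage-like, 220 in T-like, 207 in endothelial-like and 144 in microglia-like cells, where the real comparison gave 0, 1, 22 and 0 in edgeR. That points to a structure of the samples apart from the groups. Those libraries hold 29510, 38603 and 54437 barcodes, and the others 14078, 8531 and 10889. In the T-like and endothelial-like comparisons 2 of the 10 splits each gave as many genes. A real count of 0 is reached by all 10 in the other classes whatever the data, which decides nothing. The lists were 4 and 9, 4 and 7, 9 and 9, and 6 and 7, with 6, 6, 2 and 4 splits as large. For the interaction, 100 splits were drawn. In monocyte/macrophage-like cells 50 gave at least the real 6 lists (highest other 13), and in T-like cells 17 gave the real 1 gene (134) and 67 the real 4 lists (10), so chance cannot be excluded for these. The 0 genes in monocyte/macrophage-like cells were reached by all 100 by construction (highest other 396), which decides nothing.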
